A study of Harpegnathos saltator with 18 samples.

How the data were processed

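Polyadenylated RNA was measured by sequencing in 6 tissues of the ant Harpegnathos saltator, with 3 libraries per tissue and 18 libraries in all. The tissues were the ovary of gamergates (workers that mate and lay eggs) and, from workers, the fat body, the antenna, the retina, the optic lobe and the part of the brain that the labels call non-visual brain. Per the labels, RNA was taken up in TRIzol, treated with Turbo DNase, fragmented by heat with divalent cations and copied from random hexamers, and the libraries kept no strand. Reads from a gene and an overlapping antisense gene can therefore not be told apart. Whether reads shared between near-identical gene copies were split is not given in the sources used here. Every library carries the same flow-cell label, so no sequencing batch could be set against the tissues.

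The deposited values are RPKM, reads scaled by the length of the gene model and by the total of the library, with 1 column per library and no pooling of replicates. The submitters' processing notes name STAR 2.5.0b and DESeq2 and give neither a role. The genome build, the gene annotation and the counting of reads into genes are not given in the sources used here. The deposited table has 20755 rows, of which 20317 carry HSALG identifiers and 438 carry XLOC identifiers, and 18589 rows lie above 0 in at least 1 library. None of the identifiers (0 of 20755) matched the 14329 genes of the reference table used for names, so genes are given by identifier, without names or coordinates. The 34 gene lists fixed before the data were examined work on gene names and could not be applied, and the planned result on them was not run. The rule for named genes fixed at the same time then allows at most 2 identifiers higher and 2 lower per comparison. It takes those past the threshold with the largest log2 difference to the next tissue, provided that no library of the tissue overlaps with any library of the tissues it is compared with. Of the XLOC loci, the 2 enriched with the largest difference are given.

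Because RPKM values of a gene are whole multiples of what 1 read is worth in a library, gene length, library total and reads were recovered jointly from the deposited RPKM. Reads were recovered for 17551 rows, 94.4% of the rows above 0. Of all values in rows above 0, 99.49% came out whole to within the rounding of the 6 printed digits plus a relative allowance of 1.5e-06. On simulated data of 17551 genes the same procedure returned the totals of 18 of 18 libraries, and every read count of 97.8% of the recovered genes was right. The recovered library totals, which set the scale of the RPKM, ran from 2.37 M (mega) reads (antenna replicate 2) to 30.1 M (ovary replicate 2). Reads in gene models ran from 0.543 M (antenna replicate 2) to 20.2 M (ovary replicate 2), which is 19.7% (antenna replicate 1) to 67.3% (ovary replicate 2) of the total. Which reads make up the total is not given in the sources used here. Of the recovered counts from 1 to 10, between 47.4% and 67.4% were even, depending on the library, so reads cannot be taken as independent observations. Of the recovered lengths of HSALG models, 97.6% were multiples of 3, and they are called coding length here. The share was 35.3% for XLOC loci, whose lengths are given in bases. At a length of 1000 bases, 3 reads were worth 0.0998 RPKM in the deepest library and 1.27 RPKM in the shallowest, and such floors cover counting error only.

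Values were tested as log2(RPKM + 1) with limma 3.58.1 in R 4.3.3, with a mean-variance trend and without weights or blocks. All 6 tissues entered 1 fit and shared the estimate of the spread. Genes at 1 RPKM or more in at least 3 libraries were kept, 12996 in all. A gene was called enriched in a tissue when it was at least 2-fold higher than in each of the 5 other tissues and the largest of the 5 one-sided p-values had a Benjamini-Hochberg adjusted value under 0.05. Depleted genes were called in the same way in the other direction. The pairs non-visual brain and optic lobe, optic lobe and retina, and antenna and retina were compared with two-sided limma tests at the same thresholds. A log2 difference on this scale understates the change of genes near 1 RPKM. It is a difference of means of log2 values, so it can depart from the ratio of the mean RPKM printed beside it where libraries vary widely. For a gene with no read in any library of a tissue, a fold was computed against 3 reads over the libraries of that tissue together. The tissue specificity index tau was computed from the 6 tissue means of log2(RPKM + 1). It is 0 for a gene at the same level everywhere and 1 for a gene seen in a single tissue. Medians of gene sets were placed among the medians of 10000 random lists of the same size, matched in 20 classes of mean expression over libraries, and for the specificity index also of the highest tissue mean.

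The limma procedure was tested on simulated reads of 12995 genes with 200 genes changed in the optic lobe. Reads were drawn from a negative binomial distribution (counts that spread more than by counting error alone) of size 10. The shares called hold for that spread and need not hold for these libraries. Of genes raised 2, 4 and 8-fold, 3%, 77.6% and 100% were called enriched in the optic lobe, with 0 false calls. In the comparison of optic lobe and retina 17.9%, 92.5% and 100% were called higher in the optic lobe, with 1 false call. Alternatives chosen before the data were examined were pseudocounts of 0.1 and 5, no filter and a filter at 5 RPKM, and libraries rescaled to the same sum, by quantile normalization or by trimmed-mean factors. Others were limma without the trend, library weights, a replicate block, no fold minimum, a fold minimum of 4, fits of only the tissues compared, each tissue against the mean of the others, and each library left out in turn. Added after seeing the data were limma's voom on the recovered reads, reads thinned to the 542569 gene-model reads of the shallowest library, a fit without the antenna libraries, and removal of a length trend per library.

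Lists of genes high in a single tissue, the antenna aside, were made to look for RNA of other tissues in the antenna libraries, after the data had been seen. A gene was listed at a mean of 100 RPKM or more in the tissue and at least 30 times the highest mean of the other tissues outside the antenna. This gave 33 retina, 16 fat body and 56 ovary genes. As the antenna had no part in the choice, a listed gene can be high there too. HSALG011322.2 of the retina list stood at 144% of the retina level in antenna replicate 1. HSALG005185.1 of the ovary list stood at 217% of the ovary level in antenna replicate 2. The non-visual brain (3 genes) and the optic lobe (0 genes) had too few for a list. In made libraries with 0, 5 and 20% of retina RNA mixed into antenna reads, the median of the retina list read back 0.48, 5.96 and 21.15% of the retina level. Other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.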

Results

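Transcript levels were measured in 6 tissues of Harpegnathos saltator, an ant in which workers can become egg-laying gamergates. Each tissue had 3 libraries. The ovary came from gamergates. The fat body (the insect organ of storage and metabolism), the antenna (the main organ of smell), the retina, the optic lobe (the brain region that receives visual input) and the non-visual brain came from workers. Ovary and caste can therefore not be separated, and a value called enriched in ovary is a value of gamergate ovary against worker tissues. The labels do not say that replicates came from separate animals, so p-values measure only the spread between these libraries, which may be technical. The totals behind the RPKM, in units of M (mega) reads, were 11.3 to 15.2 M reads for non-visual brain, 11 to 26.5 M for optic lobe, 10.5 to 21.1 M for retina, 2.37 to 4.73 M for antenna, 8.2 to 16.2 M for fat body and 14.7 to 30.1 M for ovary.

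**Figure D1:**
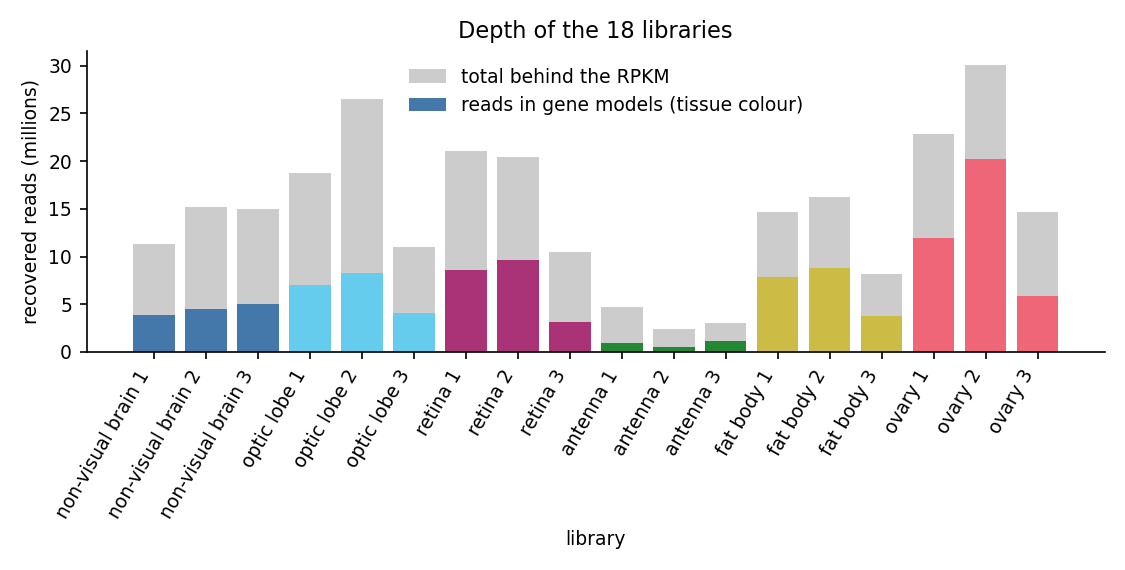
Recovered reads per library in M, with the total behind the RPKM in grey and the reads in gene models in the colour of the tissue. The 3 antenna libraries had 0.543 to 1.12 M reads in gene models, fewer than any of the 15 other libraries (3.16 to 20.2 M).

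Most libraries were closest to those of their own tissue. Pearson correlations of log2(RPKM + 1) across the 12996 genes, which are not independent replicates, averaged 0.923 within ovary, 0.9 within retina, 0.877 within optic lobe, 0.875 within non-visual brain, 0.872 within fat body and 0.606 within antenna. The 2 brain parts were the most alike of all tissue pairs (mean r = 0.829), and antenna and ovary the least (0.455). Of the 18 libraries, 13 correlated better on average with their own tissue than with any library of another tissue, and the others were the 3 antenna libraries, optic lobe replicate 3 and non-visual brain replicate 1. By the single closest library, antenna replicates 1 and 2 still paired with each other (0.646, against 0.634 and 0.636 with retina replicate 3). Non-visual brain replicate 1 was closest to non-visual brain replicate 2 (0.859, against 0.852 with optic lobe replicate 3). Antenna replicate 3 correlated at 0.726 with retina replicate 1 and at 0.587 on average with the other antenna libraries. Optic lobe replicate 3 correlated at 0.867 with non-visual brain replicate 2 and at 0.842 on average with the other optic lobe libraries. The first principal component (30.6% of the variance) set the brain parts apart from the other tissues, and the second (22.4%) set the ovary apart.

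**Figure D2:**
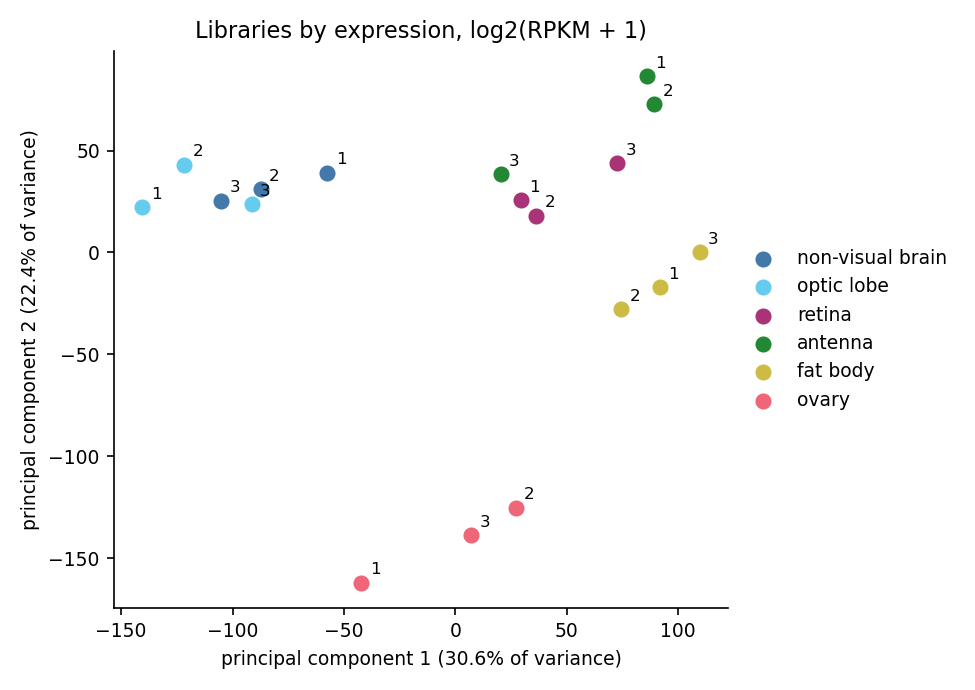
Each point is a library on the first 2 principal components of log2(RPKM + 1), in arbitrary units, with the replicate number beside it. The ovary libraries lie at -125.1 or below on the second component, and antenna replicate 3 (20.4 on the first component) lies beside retina replicates 1 and 2 (29.6 and 36.3) and away from the other antenna libraries (86.2 and 89.4).

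By the rule that compares with each other tissue, the ovary of gamergates had the largest set of enriched genes of the 6 tissues. Against the mean of the other tissues the optic lobe had more. In ovary, 590 genes were at least 2-fold above each worker tissue, with a median log2 difference of 2.81 to the next tissue, and 152 of them were at least 16-fold above it. These genes took 33.4 to 59.8% of the RPKM of the ovary libraries. Their count was 347 with a pseudocount of 0.1 and 1000 with library weights. HSALG004474.1 averaged 2204 ± 346 RPKM (SD, n = 3) in ovary and 13.6 ± 23.5 in antenna, the next tissue, a log2 difference of 9.3 (SE 0.97, adjusted p = 7.17e-07, limma). HSALG004400.2 averaged 1364 ± 323 RPKM in ovary and 6.38 ± 8.36 in non-visual brain, a log2 difference of 8.18 (SE 1.33, adjusted p = 0.000192, limma). In antenna replicate 2 these genes stood at 40.7 and 68.4 RPKM, and both were listed at 0 in the other antenna libraries. The median of the ovary list in antenna replicate 2 was 1.86% of the ovary level, against 0% in antenna replicates 1 and 3. Enriched HSALG genes had a median coding length of 1011 bases, above the range of 700.5 to 846 bases that held 95% of 10000 random lists matched on mean expression.

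Only 9 genes were depleted in ovary. HSALG012315.1 averaged 4.67 ± 4.98 RPKM in ovary against 247 ± 86.4 in fat body, the next-lowest tissue (log2 difference -5.73, SE 1.03, adjusted p = 0.0232, limma). The same gene reached 57400 ± 19500 RPKM in retina, which was 13 to 18.5% of all RPKM there. It belongs to the retina list, whose median stood at 0.3 to 0.87% of the retina level in the fat body libraries. In the ovary libraries that median was 0.05 to 0.08%. Whether traces of retina RNA in the other libraries set the difference was not tested. HSALG000603.1 averaged 2.58 ± 1.32 RPKM in ovary and 80 ± 50.3 in fat body (log2 difference -4.39, SE 0.52, adjusted p = 0.000603, limma). The count of depleted genes went from 9 to between 1 and 11 when a library was left out, to 1 with voom or a pseudocount of 5, and to 33 with trimmed-mean factors.

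In fat body, 119 genes were enriched, with a median log2 difference of 3.63 to the next tissue. They took 32 to 37.7% of the RPKM of the 3 libraries. HSALG007967.2 averaged 3205 ± 1330 RPKM in fat body and 60.7 ± 65.7 in antenna, a log2 difference of 6.15 (SE 0.76, adjusted p = 0.000466, limma). HSALG012249.2 averaged 132 ± 66 RPKM in fat body and 1.39 ± 2.4 in antenna, a log2 difference of 6.13 (SE 0.68, adjusted p = 0.000198, limma). Of the antenna libraries, replicate 3 held most of both, with 136.6 and 4.17 RPKM. Both depleted genes of the fat body were HSALG genes. HSALG028167.1 averaged 1.65 ± 1.09 RPKM there and 18 ± 1.36 in retina (log2 difference -2.92, SE 0.46, adjusted p = 0.0268, limma). HSALG001642.2 averaged 0.322 ± 0.456 RPKM there and 8.23 ± 4.73 in antenna (log2 difference -2.73, SE 0.47, adjusted p = 0.05 after rounding, limma). Its unrounded value lay just under the threshold. The count of enriched genes fell to 32 with a pseudocount of 0.1 and 64 without fat body replicate 2, and rose to 231 with trimmed-mean factors. The count of 2 depleted genes ended under the replicate block (0 genes) and moved when any of 15 libraries was left out, to between 0 and 8.

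In retina, 100 genes were enriched, with a median log2 difference of 3.52 to the next tissue, and 41 of them were at least 16-fold above it. These 100 genes took 29.3 to 31.1% of the RPKM in retina. HSALG029713.1 averaged 2473 ± 928 RPKM in retina and 221 ± 322 in antenna, a log2 difference of 6.07 (SE 1.4, adjusted p = 0.027, limma). HSALG002894.2 averaged 2972 ± 1390 RPKM in retina and 81.3 ± 91.2 in antenna, a log2 difference of 5.81 (SE 0.8, adjusted p = 0.000267, limma). Antenna replicate 3 carried 590 and 184.7 RPKM of these genes, against 0 and 12.4 in antenna replicate 1. HSALG genes enriched in retina were long, with a median coding length of 1115 bases at percentile 99.47 of the matched random lists. Those enriched in fat body, optic lobe and non-visual brain lay inside the random range, at percentiles 64.05, 49.63 and 15.64. For length, no lists matched on the highest tissue mean were drawn. No gene was depleted in retina by limma, where 77 genes had an unadjusted p under 0.05 and voom also called 0. The count enriched in retina was 46 with a pseudocount of 0.1, 151 with trimmed-mean factors, 162 with library weights and 175 without the antenna libraries in the fit.

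In antenna, 43 genes were enriched and 41 depleted. HSALG011110.1 averaged 5174 ± 3790 RPKM in antenna and 0.454 ± 0.785 in optic lobe, a log2 difference of 11.38 (SE 0.68, adjusted p = 2.9e-09, limma). HSALG011619.1 averaged 11110 ± 7980 RPKM in antenna and 4.31 ± 1.94 in optic lobe, a log2 difference of 10.59 (SE 0.73, adjusted p = 2.11e-08, limma). Both were lowest in replicate 3, at 823.5 and 1901 RPKM, against 6931 to 7767 and 15700 to 15720 RPKM in the other antenna libraries. The enriched genes took 1.89 to 17.2% of the RPKM. Enriched HSALG genes were short, with a median coding length of 580.5 bases at percentile 1.38 of the matched random lists.

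By median, the retina and fat body lists stood highest in replicate 3 of the antenna libraries. The 33 genes of the retina list lay at a median of 17.27% of the retina level in antenna replicate 3, 2.93% in replicate 2 and 0.48% in replicate 1. The 16 genes of the fat body list lay at 6.42%, 0.85% and 0.22%. A list of 13 genes that were at least 30 times higher in antenna replicates 1 and 2 than in any other tissue lay at 22.48% of that level in replicate 3. Without antenna replicate 3, limma called 74 genes enriched in antenna and 341 depleted. With all 18 libraries and a pseudocount of 0.1 it called 20 and 206. A pseudocount of 5 left 1 depleted gene.

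**Figure D3:**
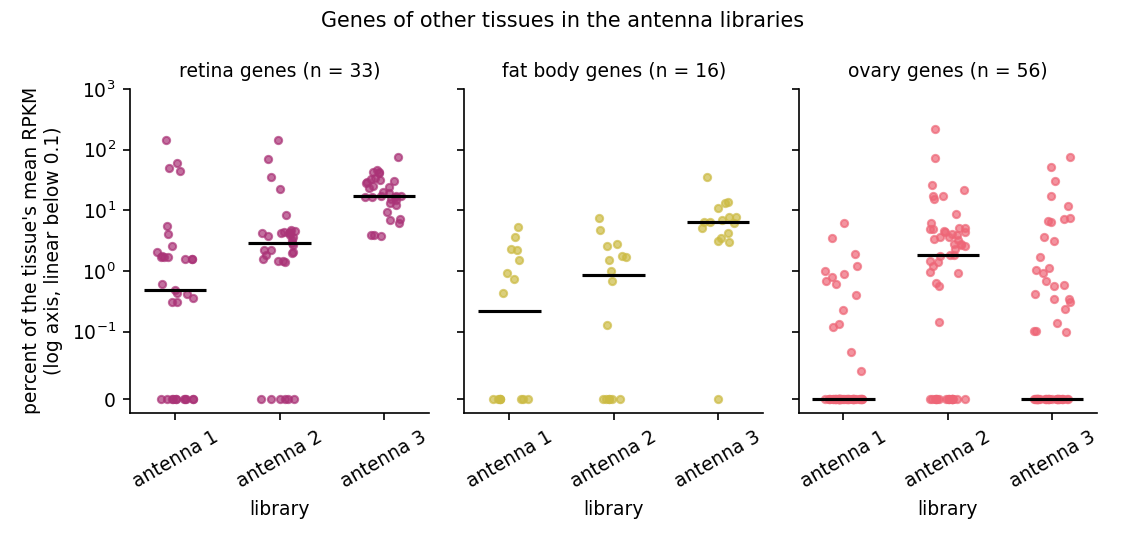
Each point is a gene listed for retina (33 genes), fat body (16) or ovary (56), with its RPKM in an antenna library as percent of its mean RPKM in the listed tissue, on a log axis that is linear below 0.1; bars mark medians. The retina median is 17.27% and the fat body median 6.42% in antenna replicate 3, while the ovary median is highest in replicate 2 (1.86%).

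Genes depleted in antenna were listed at 0 in each antenna library in both leading cases. HSALG012511.1 averaged 18.7 ± 14 RPKM in fat body, the next tissue, and was at least 11.7-fold lower in antenna than there, counting 3 reads over the 3 antenna libraries as the floor (adjusted p = 0.00727, limma). HSALG001853.1 averaged 15.7 ± 4.63 RPKM in retina and was at least 18.6-fold lower in antenna (adjusted p = 0.00058, limma). The depleted HSALG genes had a median coding length of 427.5 bases, under the range of 916.5 to 1689 bases of the matched random lists. In the shallowest antenna library 3 reads were worth 1.27 RPKM at 1000 bases and more in shorter genes, and with reads thinned to the shallowest library 14 of the 41 genes were called.

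In the non-visual brain, 44 genes were enriched, with a median log2 difference of 3.03 to the next tissue, and they took 0.97 to 1.09% of the RPKM. HSALG001442.2 averaged 266 ± 81.1 RPKM in non-visual brain and 1.26 ± 2.18 in antenna, a log2 difference of 7.26 (SE 0.62, adjusted p = 2.03e-06, limma). HSALG013198.2 averaged 396 ± 185 RPKM in non-visual brain and 3.45 ± 2.25 in optic lobe, a log2 difference of 6.48 (SE 0.68, adjusted p = 1.57e-05, limma). In the optic lobe, 77 genes were enriched, at a smaller median log2 difference of 2.1, and they took 0.52 to 0.69% of the RPKM. A single gene, HSALG013507.2, was at least 16-fold above the next tissue by the difference of mean log2 values. It was listed at 0 in antenna replicates 1 and 2, which widens that difference beyond the ratio of the mean RPKM. HSALG013507.2 averaged 52 ± 27.1 RPKM in optic lobe and 7.16 ± 12.4 in antenna, a log2 difference of 4.12 (SE 0.82, adjusted p = 0.0139, limma). HSALG027574.1 averaged 47.5 ± 19.2 RPKM in optic lobe and 4.16 ± 5.13 in antenna, a log2 difference of 3.6 (SE 0.66, adjusted p = 0.00736, limma). Of the antenna libraries, replicate 3 held most of both, with 21.5 and 10.1 RPKM.

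No gene was depleted in either brain part by limma, where 3 genes (non-visual brain) and 26 genes (optic lobe) had an unadjusted p under 0.05 and voom also called 0 for each. The number enriched in optic lobe moved with the processing. It was 2 with voom, 6 with quantile normalization, 18 with a pseudocount of 0.1, 757 with library weights, 190 without optic lobe replicate 3, 37 without replicate 1 and 40 without replicate 2. In non-visual brain voom called 15 genes, all among the 44, a pseudocount of 0.1 left 10, and library weights gave 87.

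**Figure D4:**
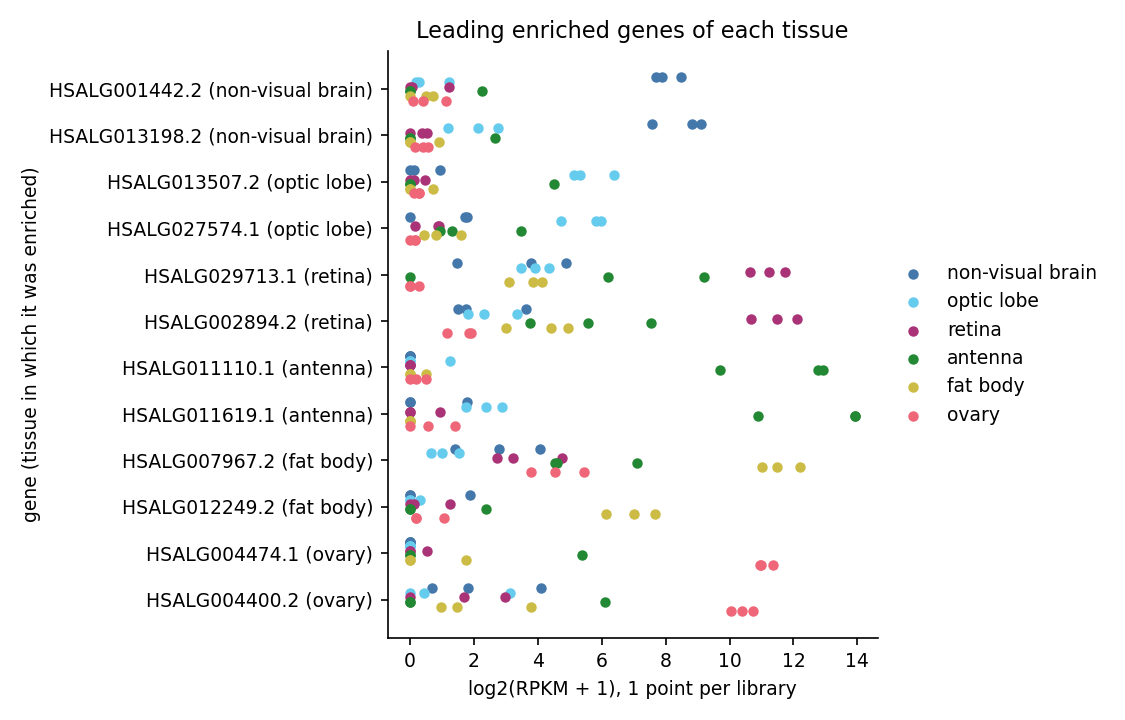
The leading enriched genes of each tissue by the fixed rule, 2 per tissue, with log2(RPKM + 1) of each of the 18 libraries as a point in the colour of its tissue. No library of another tissue overlaps with the tissue of enrichment, and HSALG011619.1 reaches 15720 RPKM in antenna replicate 1 against 6.27 RPKM in its highest library outside the antenna.

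The comparison of the 2 brain parts asks which genes differ between the non-visual brain and the optic lobe. In all, 65 genes were higher in non-visual brain and 118 were lower. HSALG001442.2 had the largest difference in favour of non-visual brain (log2 difference 7.45, SE 0.62, adjusted p = 3.69e-06, limma), with 0.562 ± 0.667 RPKM in optic lobe. HSALG005445.2 averaged 422 ± 303 RPKM in non-visual brain and 2.29 ± 3.33 in optic lobe (log2 difference 7.29, SE 0.66, adjusted p = 3.69e-06, limma). On the other side, HSALG013507.2 averaged 0.333 ± 0.502 RPKM in non-visual brain (log2 difference -5.26, SE 0.82, adjusted p = 0.00126, limma). HSALG027574.1 averaged 1.58 ± 1.38 RPKM there (log2 difference -4.34, SE 0.66, adjusted p = 0.00103, limma). The median gene differed by -0.22 on the log2 scale, and the balance of directions moved with the scaling, from 65 higher and 118 lower to 85 and 68 with quantile normalization and 60 and 70 with trimmed-mean factors. A fit of only these 2 tissues gave 28 and 28, a pseudocount of 0.1 gave 25 and 45, and library weights gave 826 and 1985. Without optic lobe replicate 3 the counts were 120 and 260, without optic lobe replicate 1 they were 44 and 61, and 69 genes were lower without optic lobe replicate 2.

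The optic lobe and the retina, which are successive stations of the visual pathway, differed in many more genes. As deposited, 3233 genes were higher in optic lobe and 479 were lower. HSALG006970.2 averaged 606 ± 273 RPKM in optic lobe and 5.7 ± 4.08 in retina (log2 difference 6.71, SE 0.56, adjusted p = 6.76e-07, limma). HSALG000567.2 averaged 192 ± 81.7 RPKM in optic lobe and 1.73 ± 1.24 in retina (log2 difference 6.17, SE 0.61, adjusted p = 2.28e-06, limma). In the other direction HSALG011742.2 averaged 0.823 ± 0.509 RPKM in optic lobe and 5405 ± 1150 in retina (log2 difference -11.55, SE 0.68, adjusted p = 9.77e-09, limma). HSALG006552.2 averaged 0.286 ± 0.429 RPKM in optic lobe and 665 ± 322 in retina (log2 difference -8.96, SE 0.61, adjusted p = 5.04e-08, limma). The median gene lay 1.02 higher in optic lobe on the log2 scale, and the 10 highest genes of a library took 39.2 to 46.6% of the RPKM in retina against 5.51 to 7.98% in optic lobe. The split of 87.1% higher calls became 91.9% with libraries rescaled to the same sum (5022 and 444 genes), 60.1% with trimmed-mean factors (1153 and 765) and 51.8% with quantile normalization (1035 and 965). The count of higher genes was 1544 without optic lobe replicate 1, 1623 without retina replicate 3, 1790 with a pseudocount of 0.1 and 6472 with library weights.

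The antenna and the retina are the dissected sense organs of the head. As deposited, 365 genes were higher in antenna and 692 were lower. HSALG011619.1 averaged 11110 ± 7980 RPKM in antenna and 0.304 ± 0.527 in retina, where 7 reads were recovered (log2 difference 12.61, SE 0.73, adjusted p = 2.6e-09, limma). HSALG011110.1 had no read in retina and was at least 29900-fold higher in antenna, with 3 reads over the 3 retina libraries as the floor (adjusted p = 2.6e-09, limma). HSALG004090.2 averaged 82.9 ± 52.8 RPKM in retina, had no read in antenna and was at least 1020-fold lower there (adjusted p = 3.64e-05, limma). HSALG029713.1 was also lower in antenna (log2 difference -6.07, SE 1.4, adjusted p = 0.00957, limma), at 0, 72.4 and 590 RPKM in the antenna libraries. Antenna replicate 3, with the retina list at 17.27% of its retina level, was 1 of the 3 antenna libraries in these counts, and without it 597 genes were higher and 1515 lower. Without retina replicate 1, 2 or 3 the counts were 242 and 424, 198 and 357, and 239 and 665. The balance moved with the scaling, to 634 higher and 599 lower with libraries rescaled to the same sum and 325 and 1588 with trimmed-mean factors. A fit of only these 2 tissues gave 75 and 323. With antenna replicate 3 and retina replicate 3 exchanged, 1020 genes were called in both directions together, against 1057 with the labels as given.

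The 369 tested XLOC loci had a median specificity index of 0.504 and the 12627 HSALG genes of 0.465, a difference of 0.039. The XLOC median lay at percentile 8.83 of 10000 random HSALG lists matched on the mean over libraries and at percentile 78.9 of lists matched on the highest tissue mean, a matching added after the data had been seen, so the 2 ID classes were not shown to differ in specificity. Without the filter on low values the difference turned to -0.071. In 4 of 5 equal classes of genes by the highest tissue mean the XLOC median was the higher (0.464 against 0.326 in the highest class with 47 XLOC loci, then 0.393 and 0.367, 0.466 and 0.417, 0.544 and 0.521), and in the lowest class it was the lower (0.647 and 0.685). Of the XLOC loci, 44.2% were highest in optic lobe and 15.7% in ovary, against 36.8% and 30.7% of HSALG genes. Among enriched genes, 20 XLOC loci belonged to ovary, 5 to fat body, 4 to retina, 2 to optic lobe, 1 to antenna and 0 to non-visual brain. XLOC_115913 (1314 bases) averaged 748 ± 249 RPKM in fat body and 21.9 ± 24 in antenna (log2 difference 5.92, SE 0.91, adjusted p = 0.00133, limma). XLOC_036982 (894 bases) averaged 55.1 ± 5.65 RPKM in ovary and 1.38 ± 1.27 in retina (log2 difference 4.69, SE 0.5, adjusted p = 1.01e-06, limma).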

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

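Tests on the recovered reads (voom, thinning), without the antenna libraries and with a length trend removed were chosen after the data had been seen, as were the counts of genes shared by 2 tissues, and the other settings before. The specificity index stayed above 0 for the difference of XLOC and HSALG medians in every setting but the missing filter. Removing the fold minimum moved no count by more than 1.5 times. The alternatives for gene lists were not run, since no identifier matched a name. Except where a reason is given, the cause of a changed count was not tested. Depth limits the antenna most: its shallowest library has 542569 reads in gene models.

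With a pseudocount of 0.1, which lets genes near 0 spread more, genes enriched numbered 10 in non-visual brain, 18 in optic lobe, 46 in retina, 20 in antenna, 32 in fat body and 347 in ovary, and depleted genes 206 in antenna and 19 in fat body. Between the brain parts 25 were higher and 45 lower in non-visual brain, and 1790 were higher in optic lobe than retina; the index was 0.354. With a pseudocount of 5, 116 genes were enriched in optic lobe, depleted genes numbered 1 in antenna, 0 in fat body and 1 in ovary, 404 were lower in antenna than retina, and the index was 0.561. Without a filter, 6 genes were depleted in fat body, the index was 0.623 and its XLOC minus HSALG difference -0.071. With the filter at 5 RPKM, 18 genes were enriched in optic lobe, 7 depleted in fat body and 40 lower in non-visual brain than optic lobe, with an index of 0.404. A fold minimum of 4, stricter by construction, left 45 genes enriched in optic lobe, 78 lower in non-visual brain than optic lobe and 1970 higher in optic lobe than retina.

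With libraries rescaled to the same sum, 7 genes were depleted in fat body and 15 in ovary, 5022 were higher in optic lobe than retina and 634 higher in antenna than retina. With quantile normalization, 6 genes were enriched in optic lobe, depleted genes numbered 16 in antenna, 1 in fat body and 32 in ovary, 68 were lower in non-visual brain than optic lobe, 1035 higher and 965 lower in optic lobe than retina, and the index was 0.393. With trimmed-mean factors, enriched genes numbered 36 in optic lobe, 151 in retina and 231 in fat body, and depleted genes 102 in antenna and 33 in ovary. There, 70 were lower in non-visual brain than optic lobe, 1153 higher and 765 lower in optic lobe than retina, and 1588 lower in antenna than retina, with an index of 0.435. Limma without the trend gave 43 genes enriched in optic lobe and 6 depleted in fat body. Removing a length trend gave 5 depleted in fat body.

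Library weights ran from 0.16 (antenna replicate 3) to 11 (retina replicate 1), with 0.29 and 0.3 for the other antenna libraries, 0.38 for optic lobe replicate 3 and 0.39 for non-visual brain replicate 1. They gave 87 genes enriched in non-visual brain, 757 in optic lobe, 162 in retina and 1000 in ovary. Depleted genes then numbered 12 in antenna, 4 in fat body and 21 in ovary. Between the brain parts 826 were higher and 1985 lower in non-visual brain, 6472 were higher and 968 lower in optic lobe than retina, and 208 were higher in antenna than retina. In fits of only the tissues compared, with 6 libraries, 28 genes were higher and 28 lower in non-visual brain than optic lobe, and 75 higher and 323 lower in antenna than retina. Against the mean of the 5 other tissues, a looser question by construction, enriched and depleted genes numbered 1459 and 295 in non-visual brain, 3620 and 529 in optic lobe, 483 and 616 in retina, 532 and 2628 in antenna, 692 and 2584 in fat body, and 2683 and 1287 in ovary.

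Voom gave 15 genes enriched in non-visual brain, 2 in optic lobe and 24 in antenna, 75 depleted in antenna, 11 in fat body and 1 in ovary, and 51 lower in non-visual brain than optic lobe. Of its calls, these were also called on log2(RPKM + 1): enriched, 397 of 419 in ovary, 83 of 111 in fat body, 73 of 83 in retina and 22 of 24 in antenna; depleted, 37 of 75 in antenna and 1 of 11 in fat body. In the pairs it was 29 of 44 higher and 38 of 51 lower in non-visual brain than optic lobe, 2569 of 2943 and 428 of 516 in optic lobe than retina, and 201 of 299 and 522 of 669 in antenna than retina. Reads thinned to the shallowest library gave 50 enriched in optic lobe, 14 depleted in antenna, 0 in fat body and 4 in ovary, and 436 lower in antenna than retina. Without the antenna libraries, enriched genes numbered 145 in optic lobe, 175 in retina and 187 in fat body, depleted genes 21 in fat body and 21 in ovary, 215 were lower in non-visual brain than optic lobe and 4929 higher in optic lobe than retina.

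The replicate block took the depleted genes of fat body from 2 to 0 and the genes higher in both retina and antenna from 11 to 6, and moved no other count by more than 1.5 times. Libraries share replicate numbers across tissues, and no clear pairing by number was seen. The deviations of same-numbered libraries correlated at -0.001 on average over 45 pairs (-0.35 to 0.333), and 8 of 18 libraries correlated best with their own number. With pairs that vary this widely, a pairing by animal or by handling cannot be excluded.

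Leaving out each library in turn gave these ranges. Enriched genes ran from 37 (without optic lobe replicate 1; 40 without replicate 2) to 190 (without optic lobe replicate 3) in optic lobe, from 37 to 74 (without antenna replicate 3) in antenna, and from 64 (without fat body replicate 2) to 157 in fat body. Depleted genes ran from 24 (without retina replicate 1 or 2 or fat body replicate 2) to 341 (without antenna replicate 3) in antenna, with 68 and 70 without antenna replicates 1 and 2. They ran from 0 to 8 in fat body, where 15 libraries moved the count, and from 1 (without ovary replicate 2) to 11 in ovary, with 3 without retina replicate 2, 4 without fat body replicate 1 or ovary replicate 1 and 5 without ovary replicate 3. Higher and lower in non-visual brain than optic lobe were 44 to 120 and 61 to 260 genes, both lowest without optic lobe replicate 1 and highest without optic lobe replicate 3, with 69 lower without optic lobe replicate 2. Higher in optic lobe than retina were 1544 (without optic lobe replicate 1) to 4156 genes, with 1955 without optic lobe replicate 2 and 1623 without retina replicate 3. Higher in antenna than retina were 198 (without retina replicate 2) to 597 genes (without antenna replicate 3), with 242 and 239 without retina replicates 1 and 3. Lower were 357 (without retina replicate 2) to 1515 genes (without antenna replicate 3), with 424 without retina replicate 1. The 7 other counts stayed within 1.5 times, and the XLOC minus HSALG difference ran from 0.02 to 0.046.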

Other observations

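The tests of admixture, length and scaling and the counts of genes shared by 2 tissues were chosen after the results were seen, and the thresholds for reading the splits of the libraries were written down after too, except those for the shared genes, which came before their splits were run. The brain parts shared a set of genes that no other tissue matched. In limma, 194 genes were at least 2-fold higher in both non-visual brain and optic lobe than in each of the 4 other tissues, 7 of them XLOC loci, against 44 and 77 enriched in each part alone. That order turned under library weights (345 against 87 and 757), and with quantile normalization the counts were 41 against 39 and 6. The count ran from 115 (without ovary replicate 3) to 308 (without antenna replicate 3) when a library was left out, fell to 41 with quantile normalization or voom, 75 with trimmed-mean factors, 88 with a pseudocount of 0.1 and 105 with thinned reads, and rose to 292 with libraries rescaled to the same sum, 345 with library weights and 780 without the antenna libraries. Leaving out any of 8 libraries moved it past 1.5 times. Retina and antenna shared 11 such genes with antenna replicate 3, where the retina list stood highest of the antenna libraries, and 10 without it. The median length of those 11 was 294 bases. The count was 1 with a pseudocount of 0.1, 2 with voom, 4 with thinned reads, 5 without a filter, 6 under the replicate block and 7 with library weights, and ran from 3 to 14 over the libraries left out. The other pairs of tissues shared 0 or 1.

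In 2787 genes all 18 libraries reached 1 RPKM, and in 4454 genes the 15 libraries outside the antenna did. Gamergate ovary had 169 genes that reached 1 RPKM in its 3 libraries and in no other library, against 29 in optic lobe, 17 in retina, 12 in non-visual brain, 11 in antenna and 1 in fat body. Antenna replicate 3 may lower these counts for retina and fat body. It held 33 of 33 retina list genes and 15 of 16 fat body list genes at 1% or more of their tissue level. Antenna replicate 2 may lower the count for ovary, as it held 33 of 56 ovary list genes at 1% or more of the ovary level. Thinned to the reads of the shallowest library, 11977 ± 833 genes (SD, n = 3) had a read in optic lobe, 11299 ± 1239 in non-visual brain, 10225 ± 742 in ovary, 9694 ± 568 in retina, 8298 ± 716 in fat body and 7477 ± 872 in antenna.

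Antenna replicate 3 held transcripts of the retina list at a median of 17.27% of the retina level over 33 genes. A retina library under an antenna label is argued against by the 13 genes of the antenna list, which stood at a median of 22.48% of the antenna level there and at most 0.23% in any library of another tissue. The low level in other tissues follows from how the list was chosen, but antenna replicate 3 had no part in that choice. Reads leaking in from the other libraries in proportion to their depth are argued against too: antenna replicate 3 held 0.0194% as many reads of the ovary list as the ovary libraries, and 2% as many of the retina list as the retina libraries. A leak from the retina libraries would bring the genes of a library at a single share. Of the 33 genes, 11 lay over 2-fold off the best mix of the retina libraries (10 to 12 with a gene left out). The same count was 0 in each of 20 simulated leaks, and 1, 1 and 6 for retina libraries set against the other retina libraries. Of the 11 genes in antenna replicate 3, 7 lay below the mix and 4 above, while at most 1 lay below for a retina library. Some listed genes were high in antenna replicates 1 and 2 as well. HSALG011322.2 stood at 144 and 69.88% of the retina level there, and HSALG022418.1 at 60.17 and 145.9%. Expression in the antenna itself adds to a gene, so it can account for genes above the mix but not for the 7 below. These 7 genes argue against a leak from the retina libraries as the whole cause for the retina list. As the whole cause of the fat body transcripts, such a leak is argued against. The fat body list stood at a median of 6.42% (lower quartile 4.08%) of the fat body level in antenna replicate 3. In the retina libraries it stood at 0.31 to 1.18%. RNA of retina or other head tissue in the sample stays open for both lists, as does a leak from the retina libraries as part of the cause for the retina list. That 33 of the 33 retina genes reached 1% of the retina level, with the 5 most abundant at 3.89 to 45.54%, restates the pattern and supports neither. No biological explanation was tested.

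Optic lobe replicate 3 lay the furthest toward the other brain part of the 6 brain libraries. Placed from 0 (the other optic lobe libraries) to 1 (non-visual brain) by genes chosen without it, it stood at a median of 0.61 on 625 genes higher in optic lobe and 0.57 on 246 genes higher in non-visual brain, where the other optic lobe libraries stood between -0.08 and 0.13. Non-visual brain libraries, placed in the same way from their own part to the other, stood between 0 and 0.41, with replicate 1 at 0.41 on 199 genes and replicate 3 at 0.34 on 352 genes. The deviations of optic lobe replicate 3 fell with coding length (Spearman rho -0.31 across 6867 genes, which are not independent), but removing that trend left 178 calls between the brain parts, against 183 before and 380 without this library, so the trend is not the whole cause. RNA of the non-visual brain in the sample, as the whole cause, is argued against. The 20 genes at least 16-fold higher in non-visual brain lay at a median of 3.2% (quartiles 0.91 and 10.87%) of their level there. Their median in the other optic lobe libraries, by which they were chosen, was 1.73%. In contrast, 21 genes at least 8-fold higher in the other optic lobe libraries than in non-visual brain lay at 47.5% of their level. A smaller share of such RNA stays open. A difference between animals or in RNA quality stays open too and was not tested. Optic lobe replicate 3 was also shallower, with a total of 11 M reads against 18.8 and 26.5 M in the other optic lobe libraries. Whether depth bears on its position was not tested.

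Calls between optic lobe and retina were mostly higher in optic lobe, and the median gene lay 1.02 higher on the log2 scale. The dominant genes of the retina are not the whole cause, since with 72 genes (the 10 highest of each library) kept out of the sum, the median difference was 0.76, and 0.66 to 0.93 with a library left out, against 1.34 with them in the sum. Whether a single scale factor per library explains the rest cannot be told apart from a lower level of most genes in retina, because relative values keep no absolute scale: under trimmed-mean factors 60.1% of the calls were higher in optic lobe.

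Other splits of the 18 libraries into 6 groups of 3 were fitted 100 times, the real split included. As many genes were called in 1 of 100 splits, the real one, for genes enriched in non-visual brain (44, highest other split 12), optic lobe (77, 70), retina (100, 62), antenna (43, 0), fat body (119, 62) and ovary (590, 65), for genes depleted in antenna (41, 0) and fat body (2, 0), for both brain parts (194, 0) and for retina and antenna (11, 0). For genes depleted in ovary it was 2 of 100 (9, highest other 11). Under the settings as reported this argues, at the 5% level, against libraries that do not differ by tissue. It cannot show that a given count is free of chance calls. The other splits mix tissues within a group, which puts tissue differences into the spread and can lower their counts. The splits were also not fitted under other settings, where some of the counts nearly vanish. The 2 genes depleted in fat body were 0 under the replicate block, the 9 depleted in ovary fell to 1 with voom or a pseudocount of 5, the 41 depleted in antenna to 1 with a pseudocount of 5, the 77 enriched in optic lobe to 2 with voom and 6 with quantile normalization, and the 11 shared by retina and antenna to 1 with a pseudocount of 0.1 and 2 with voom. Nothing rests on the splits for these. For the counts of 0 depleted genes in non-visual brain, optic lobe and retina, all 100 splits gave as many, and the splits say nothing. Between 2 tissues there are 10 splits of 6 libraries, too few for a share under 0.05, with the real split alone (1 of 10) reaching its count each time. The real and the highest other counts were 183 and 149 for the brain parts, 3712 and 1 for optic lobe and retina, and 1057 and 1020 for antenna and retina. The highest other split exchanged optic lobe replicate 3 with non-visual brain replicate 3 for the brain parts, and antenna replicate 3 with retina replicate 3 for antenna and retina.

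Length trends within a tissue were present in other libraries too. The rank correlation of a library's deviation with coding length was 0.49 in ovary replicate 1 and -0.31 in ovary replicate 3, and genes in the longest of 5 length classes lay 1.24 above the other ovary libraries in replicate 1.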
